A study of Homo sapiens
Mus musculus with 6 samples.

How the data were processed

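Total RNA of the xenograft tumours was pooled per cell clone, labelled with digoxigenin and hybridised to 1-colour mouse expression arrays, per the labels' protocols. The tumours are mixtures of human cancer cells and mouse stroma, so a mouse probe may also bind human RNA. Probe sequences were not used here, so this was not measured. The deposited file of each array gives a raw signal intensity, a signal-to-noise score and a flag for each probe, per the file headers. The scanner software and its background correction are not given in the sources used here. No identified probe had a raw intensity at or below 0, while 123 of 303 rows without identifier had a value below 0 on at least 1 array, so the deposited intensity was taken as already background-subtracted. For the identified probes this is an assumption. On control 25, for example, mCG145763 had a raw value of 602.6 at a signal-to-noise score of -1.49, so an offset may remain. The rows without identifier, 0.91% of all rows, were kept out of normalisation and tests. The series' value table holds linear intensities that the authors had normalised between arrays. Its 6 columns share 1 distribution (median 1214), and each column has the rank order of the raw intensity of its own array (Spearman correlation 1), as quantile normalisation gives. The submitters' processing notes name R 2.3.1. No file column belonged to a sample outside the series.

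Raw intensities of the 33012 identified probes were quantile-normalised between the 6 arrays, floored at 1 and taken to log2 in R 4.3.3 with limma 3.58.1. The resulting values lay within 0.087 log2 units of the authors' table. A probe was tested when its signal-to-noise score was at least 3 on at least 2 of the 3 arrays of at least 1 group, which kept 15546 probes. The brightest probe over all 6 arrays stood for each identifier, which left 14663 genes. Another probe of the identifier was detected for 750 identifiers, and the difference between groups had the same sign for 56.1% of these pairs of probes, so the probes of an identifier often disagreed. Podoplanin and control arrays were compared with lmFit and eBayes without covariates, with Benjamini-Hochberg adjustment over all genes tested. The thresholds were an adjusted p of 0.05 and, as a looser count, an unadjusted p of 0.05 with at least 1.5-fold. The fold of a named gene compares the mean of the brighter group with the mean over the dim arrays. A dim array entered with the higher of the probe's own value and the lowest value of a detected probe. Such a fold is an estimate and no lower confidence limit. The thresholds of 1.5-fold and 2-fold use the plain difference of the group means. The number of arrays limits the precision. The p-values measure the spread between arrays. With 1 pool and 1 array per clone, this spread holds differences between clones and error of labelling, hybridisation and scan together.

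The design, the thresholds, most alternatives and the rule for named genes were fixed before the data were examined. The rule was to name Pdpn, members of 26 fixed gene lists, and the genes with the smallest p among those at least 1.5-fold apart with groups that do not overlap. Gene symbols were not attached. The files give the identifiers without symbols, and the only gene table used here is of human genes, so the identifiers of a mouse array had no counterpart in it (0 of 30988 matched); with a mouse annotation they might be named. The podoplanin gene and the lists, lymphatic and blood endothelium among them, were therefore not analysed here. For the same reason only 2 identifiers per direction are named, those with the smallest p.

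The limma step was tested on simulated data in 5 simulations with the means and spreads of the 14663 genes and 200 changed genes. The noise was drawn independently for each gene, with the same spread on all 6 arrays. It therefore leaves out deviations that genes share and the wider scatter of control 25. Unchanged genes fell under an unadjusted p of 0.05 in 5.40% of cases. Genes changed 2-fold fell under it in 61.5%, those changed 4-fold in 89.9% and those changed 8-fold in 96.1% of cases. The alternatives were median and 75th percentile scaling, normexp background correction with an offset of 50, the authors' table, no detection filter, detection on all 6 arrays, each probe by itself, a trended robust prior, array weights, a plain t-test and leaving out each array. Added after seeing the data were a limit on flags of 5000, leaving out control 25 together with podoplanin 14, the shares by signal under other filters, and the counts of genes detected in 1 group alone, with and without each array. The files gave no slide or scan batch.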

Results

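Mouse transcripts were measured in xenograft tumours of MCF7, a human breast carcinoma line, grown in the mammary fat pads of nude mice. The cancer cells carried either human podoplanin, a membrane glycoprotein known from lymphatic endothelium, or the empty vector. The series asks how podoplanin on the cancer cells relates to gene expression in the mouse stroma of the tumour. There were 3 podoplanin clones (6, 11 and 14) and 3 control clones (4, 9 and 25). Each clone gave 1 array, hybridised with RNA pooled from 10 tumours of 5 mice after 24 days of growth. The clone is therefore the replicate, and n = 3 per group. Each 1-colour array held 33012 probes with a gene or transcript identifier, for 30988 different identifiers. The files used here give no gene symbols for these identifiers, so genes are described by identifier and by group.

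The control tumours of clone 25 gave a dimmer array than the other 5. A probe was called detected when its signal-to-noise ratio was at least 3. By this rule 34.6% of the probes were detected on control 25, against 45.2% on control 4 and 44.8% on control 9. The podoplanin arrays lay close together, with 45.1% for clone 6, 45.4% for clone 11 and 47.4% for clone 14. The group means were 41.6% ± 6.00 for control and 45.9% ± 1.24 for podoplanin (SD, n = 3 each), and the two-sided exact permutation test gave p = 0.2. The median raw signal was 1054 ± 146 units in the control arrays and 1414 ± 151 units in the podoplanin arrays (SD, n = 3 each). It was higher on every podoplanin array than on every control array, and the two-sided exact permutation test gave p = 0.1, the smallest value that 3 arrays against 3 allow.

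**Figure D1:**
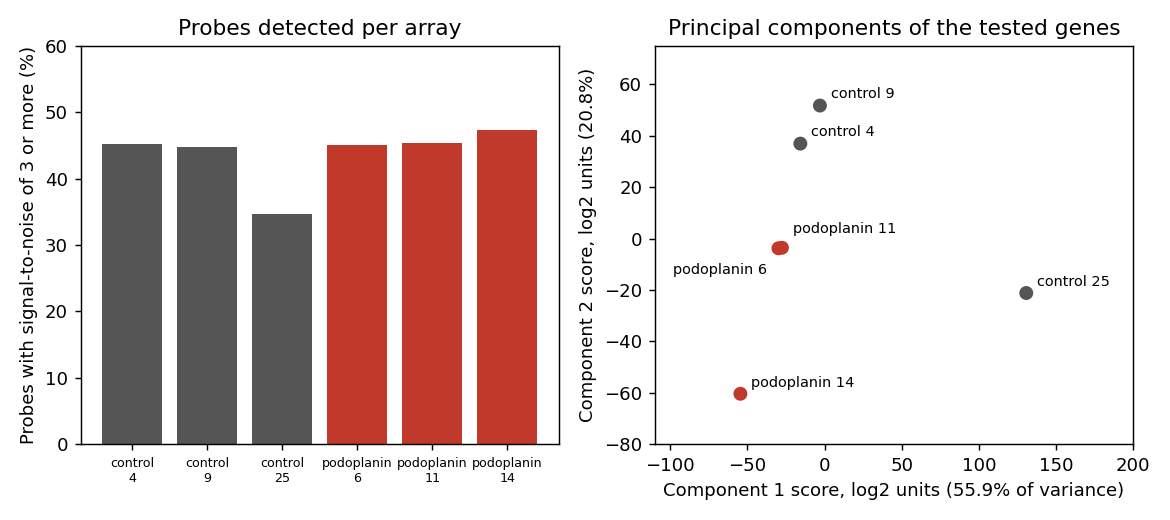
Left, the percentage of probes with a signal-to-noise ratio of at least 3 on each array, with control clones in grey and podoplanin clones in red. Right, the scores of the 6 arrays on principal components 1 and 2 of the tested genes (quantile-normalised log2 signal), where control 25 lies at 131 on component 1 and the other 5 arrays have negative scores, down to -54.5 for podoplanin 14.

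The array of control 25 also ranked genes differently from the others. Among the 8749 genes detected on all 6 arrays, the rank correlation across genes of control 25 with the other arrays was between 0.745 and 0.841, while it was between 0.870 and 0.983 among the other 5. Genes are not independent replicates, so these correlations describe the arrays only. The first principal component of the tested genes held 55.9% of the variance and set control 25 apart from the rest. The second held 20.8%. On it, controls 4 and 9 scored 37.0 and 51.8, podoplanin 6 and 11 scored -3.74 and -3.53, and podoplanin 14 scored -60.4. Control 25 scored -21.2, among the podoplanin arrays, so this component did not separate the groups. The median SD of a gene between clones was 0.55 log2 units in the control group and 0.31 in the podoplanin group. It was 0.20 between controls 4 and 9 alone, and 0.17 between podoplanin 6 and 11 alone.

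The comparison of podoplanin with control tumours covered 14663 genes. No gene passed an adjusted p of 0.05 in limma, where the smallest adjusted p was 0.350. At an unadjusted p under 0.05, 2038 genes differed, of which 1210 were higher and 828 lower in the podoplanin tumours, and each of them differed by at least 1.5-fold. By chance, 5% of the genes, or 733, would lie under this p if the choice of genes were blind to the groups. The detection filter is not blind, since it keeps a dim gene that only 1 group reaches. Without the filter 2645 of 30988 genes were past this p and 1.5-fold. Among genes detected on all 6 arrays 1712 of 8749 were, and both shares lie above 5%. A trended, robust prior in limma also left 0 genes past an adjusted p of 0.05, with 2208 genes at an unadjusted p under 0.05. The looser count fell most without podoplanin 14. With at least 1.5-fold it was 815 of 13763 genes without that array, not far above 5%. It was 1196 without podoplanin 6 and 1350 without podoplanin 11. With podoplanin 14 and control 25 both left out it was 1888 of 13330 genes, and 1013 of the 2038 were among these in the same direction. That setting keeps the closer 2 clones of each group, and their smaller spread by itself lowers p. It therefore cannot tell whether the 2038 genes rest on podoplanin 14. When limma estimated a weight for each array, 129 genes passed an adjusted p of 0.05, 78 of them higher and 51 lower in the podoplanin tumours. The weights, estimated from the same arrays, were 0.114 for control 25 and 0.520 for podoplanin 14. With control 25 left out instead, no gene passed, and the weighted fit was not part of the simulation. Changes were also simulated in 200 of the 14663 genes, with the spread of each gene. The adjusted threshold was passed by 0.90% of the genes changed 2-fold, 25.4% of those changed 4-fold and 57.6% of those changed 8-fold. The simulated noise was independent between genes and equal on all 6 arrays, unlike control 25, which varied more. These shares are therefore only a rough guide.

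**Figure D2:**
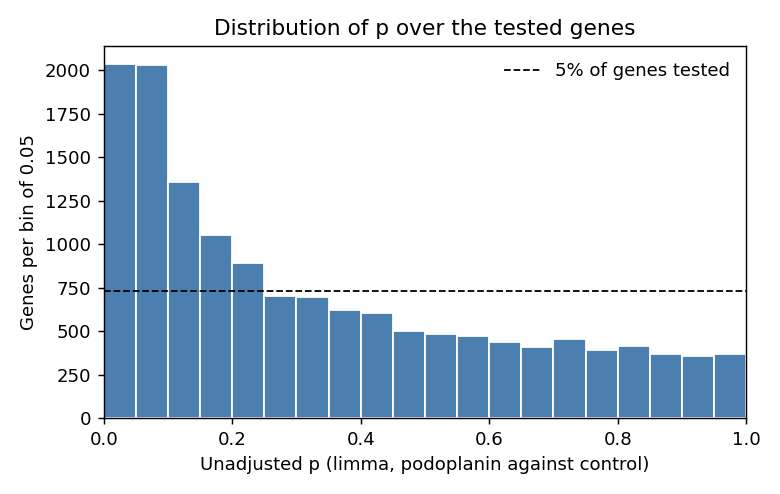
Number of genes in each bin of unadjusted p from limma for podoplanin against control (x axis, bins of 0.05; y axis, genes out of 14663). The lowest bin holds 2038 genes, above the dashed line at 733 genes, which marks 5% of the genes tested.

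The genes were spread unevenly over the 2 directions, and the split depended on how the arrays were scaled and on the detection filter. With quantile normalisation, 59.4% of the genes at an unadjusted p under 0.05 were higher in the podoplanin tumours. With each array scaled to its median the share was 72.0%, and with scaling to the 75th percentile it was 49.8%. Among genes detected on all 6 arrays, 47.7% of those past the same p and 1.5-fold were higher (816 against 896 lower), and without a detection filter 51.3% were (1356 against 1289). The median log2 difference over all tested genes was 0.10 with quantile normalisation, 0.26 with median scaling and 0.02 with 75th percentile scaling, so differences near these sizes carry no direction of their own. Of the tested genes, 4537 had groups that did not overlap (30.9%). Chance gives 10% for genes chosen without regard to group, but the detection filter uses the groups, so 10% may be too low here. Among the 4537 were 994 genes at least 2-fold higher and 610 genes at least 2-fold lower in the podoplanin tumours.

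Some genes were detected in 1 group alone. Of the 30988 identifiers, 199 were detected on all 3 podoplanin arrays and on no control array, and 53 on all 3 control arrays and on no podoplanin array. Control 25, with fewer detected probes, weighed on this split. Without it, 243 genes were detected on the podoplanin arrays alone and 216 on controls 4 and 9 alone. Leaving out any 1 array gave between 408 and 604 genes in total, against 252 with all 6, since fewer arrays then had to meet the rule. These counts rest on the detection limit, and no error model was fitted to them.

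The gene with the smallest p was mCG145763, which was detected on all 3 podoplanin arrays and on no control array. Its log2 signal was 12.91 ± 0.48 in the podoplanin tumours and 9.55 ± 0.28 in the control tumours (SD, n = 3 each), 10.3-fold higher. The difference was 3.36 log2 units with a standard error of 0.35 and an adjusted p of 0.350 in limma. The gene mCG134305.1, also detected on all 3 podoplanin arrays alone, had log2 signals of 11.41 ± 0.48 against 8.83 ± 0.20. It was an estimated 5.90-fold higher, with no control value above the detection limit. In the other direction, mCG130613.1 was detected on all 3 control arrays and on 1 podoplanin array. Its log2 signal was 8.77 ± 0.91 in the podoplanin and 12.37 ± 0.40 in the control tumours, and 2 of the podoplanin values are not above the detection limit. The undetected value of podoplanin 11 (9.80) lay above the detected value of podoplanin 6 (8.42), so no size of the difference is given. The gene AK018390.1 was detected on all 3 control arrays and on no podoplanin array. Its log2 signal was 8.93 ± 0.40 in the podoplanin and 11.22 ± 0.23 in the control tumours. It was an estimated 4.66-fold lower in the podoplanin tumours, with no podoplanin value above the detection limit. None of these 4 genes passed the adjusted threshold in the equal-weight fit (adjusted p = 0.350 for each in limma), and all 4 did with array weights (adjusted p = 0.034). Those weights were estimated from the same arrays. With control 25 left out instead, the adjusted p in limma was 0.219 for each. Each is the probe of an identifier with 1 probe on the array, so no further probe checks it.

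**Figure D3:**
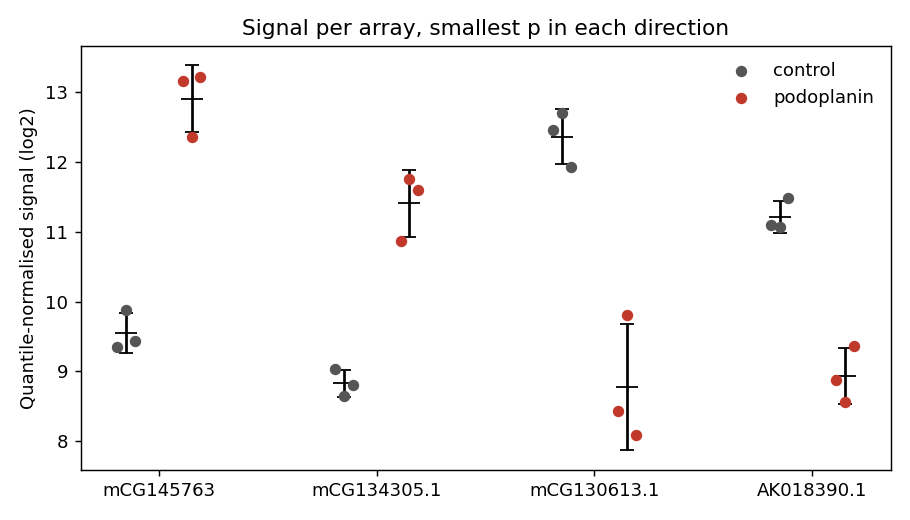
Quantile-normalised log2 signal (y axis) of the 2 genes higher and the 2 genes lower in podoplanin tumours with the smallest p (x axis); points are arrays, with control in grey and podoplanin in red, and bars give the mean and SD of 3 arrays. For mCG145763 the means are 9.55 in control and 12.91 in podoplanin tumours, and the groups do not overlap for any of the 4 genes.

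The share of genes at an unadjusted p under 0.05 varied with signal, in a way that depended on the detection filter, which keeps a dim gene that only 1 group reaches. In the dimmest 25% of the tested genes, 742 of 3666 (20.2%) were past this threshold, 472 higher and 270 lower in the podoplanin tumours. In the brightest 25%, 311 of 3666 (8.48%) were past it, 213 higher and 98 lower. Without the filter the shares past the same p and 1.5-fold were 5.11% in the dimmest and 7.42% in the brightest 25%, and among genes detected on all 6 arrays they were 22.0% and 13.1%, so no order by signal held in all 3 settings. By type of identifier, 1812 of 13338 genes named by mCG identifiers (13.6%) and 169 of 948 genes named by AK accessions (17.8%) were past the threshold, as were 44 of 235 genes named by NM accessions (18.7%) and 11 of 128 named by BC accessions (8.59%). The shares of AK and mCG genes, the 2 largest types, differed in a two-sided Fisher's exact test over genes (p = 3.8e-04), in which genes are not independent. AK genes were dimmer, with 45.3% of them in the dimmest 25%. Within the 4 classes of signal, the exact Mantel-Haenszel test no longer separated the 2 types (p = 0.14). Of the genes past the threshold, 59.8% of AK and 59.3% of mCG genes were higher in the podoplanin tumours (Fisher's exact test, p = 0.93).

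Separate probes of 1 identifier gave a partial check of the direction. Of the 2038 genes, 76 had another detected probe with the same identifier. That probe differed in the same direction for 51 genes (67.1%, 95% exact binomial interval 55.4 to 77.5%). Its median difference in that direction was 0.34 log2 units, against 1.04 for the probe tested. The same threshold was passed by 9 of these probes in the same direction and by 4 in the opposite direction.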

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

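Of the tests in this part, those of the rows without identifier, of signal loss, of noise at low signals, of control 25 as the source of the small p and of scaling were chosen after the results were seen, as was the lower of the bounds named below. The tests over probe pairs and over other splits of the arrays were fixed before their results were seen.

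The 303 rows without identifier were not part of the comparison, and some held signal above that of the control arrays. Of the 135 rows with a signal-to-noise score of at least 3 on all 6 arrays, 11 were higher on all 3 podoplanin arrays than on all 3 control arrays after scaling each array to the 75th percentile of its identified probes. Lower on all podoplanin arrays were 70 rows. In raw signal 27 rows were higher and 3 lower. The direction thus turned with the scaling, which moves all rows of an array together, so these counts show no group difference of their own. What these rows measure is not given in the sources used here.

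Control 25 stood apart from the other 5 arrays. Its log2 raw signal over the 8749 genes detected everywhere had an SD of 0.95 against the mean of the other arrays, 1.43 times the largest such SD of the other 5 (95% bootstrap interval 1.40 to 1.47). The interval covers the genes of these arrays and no spread between arrays. Control 25 was singled out as the array most apart, so a ratio over 1 was likely beforehand. A uniform loss of signal on that array would leave the ratio at or under 1, so such a loss does not account for the whole pattern. The lower rank correlation of control 25 over the same genes, which a uniform factor cannot cause, shows the same scatter, so the ratio adds no separate evidence. Noise of low signals is argued against as the whole cause too, since the ratio was 1.56 (1.49 to 1.65) in the brightest 25% of these genes; the bound for both tests was first set at 1.5 and lowered to 1. Independent error of single probes stays open: over 750 pairs of probes with 1 identifier the deviation of control 25 correlated at only 0.121 (permutation p = 0.0012). The same measure was 0.116 for podoplanin 11 and between 0.155 and 0.248 for the remaining arrays. A difference of that clone is a biological explanation that was not tested. The rows without identifier were dim on that array too (median 26349, against 47149 to 57655 on the others), and the 75th percentile of its identified probes was 10.4% of that median, against 9.99 and 9.20% on controls 4 and 9. With the mean in place of the 75th percentile, control 25 was the lowest of the 6 arrays (43.5%), so whether its share of mouse RNA was lower stays open.

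The excess of small p between podoplanin and control was weighed next. Of the 10 ways to split the 6 arrays into 3 and 3, only 1, the real one, gave as many as 2038 genes, and the highest of the others gave 703, but 10 splits are too few for a share under 0.05. Control 25 alone does not explain the excess, since 2462 genes lay past p 0.05 and 1.5-fold without it. Without podoplanin 14 there were 815 of 13763 genes, not far above the 5% of chance, so most of the excess was lost without that array. Without podoplanin 6 there were 1196 and without podoplanin 11 there were 1350. A fit with 1 array fewer also has less power, so whether podoplanin 14 is the source of the excess stays open. With control 25 and podoplanin 14 both left out there were 1888, and 1013 of the 2038 genes were among these in the same direction. This keeps the clones with the smaller spread in each group, which by itself lowers p, so it does not settle the part of podoplanin 14. Scaling each array by 1 factor in place of quantile normalisation left 1873 genes with the median and 2255 with the 75th percentile. At 5% of the genes tested, 733 would be past p 0.05. The normexp setting was still quantile-normalised and is no other scaling. The choice between these scalings is thus argued against as the source of the excess, although it moved the split of directions, as given above. Of 76 genes, 67.1% had another probe with the same direction (exact binomial p = 0.0038). This argues only weakly against independent error of single probes for the set as a whole. The test takes the genes as independent, although all come from the same 6 arrays, and over all 750 pairs the share was 56.1%. The correlation of the differences over all 750 pairs was only 0.159 (permutation p = 4e-04), which leaves the part of such error in single genes open.

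The adjusted count was 0 in each of the 10 splits, so it cannot separate the real split from the others. The count of genes detected in 1 group alone was 252 in the real split, the highest among the 10 splits (1 of 10), and the highest of the others was 146. Here too the splits are too few for a share under 0.05.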

How the results depend on the processing

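The count of genes past an adjusted p of 0.05 stayed at 0 in each of the other settings run, except with array weights, where it was 129; the smallest adjusted p over the alternatives ran from 0.034 with array weights to 0.685 without podoplanin 14. The count at an unadjusted p of 0.05 and 1.5-fold rose from 2038 to 3200 with array weights, and it ranged from 815 to 2637 when each array was left out in turn, with the lowest value without podoplanin 14 and the highest without control 4. Of the 2038 genes, 708 remained past this threshold in the same direction without podoplanin 14, 1442 without control 25 and 1013 without both. The other settings kept the count within 1.5 times, between 1437 with the plain t-test, which had 1776 genes at an unadjusted p under 0.05, and 2645 without a detection filter. The share of the genes tested varied more than the count. It was 2645 of 30988 without a filter, 2038 of 14663 in the main setting and 1712 of 8749 among genes detected on all 6 arrays. The count of genes detected in 1 group alone rose from 252 to between 408 and 604 when 1 array was left out, as fewer arrays then have to meet the rule. The 4 named genes kept their direction in the 17 alternatives that tested them. They were chosen on the same arrays for groups that do not overlap, so this was all but given and is no further support. The gene lists and the block on slide or scan were not run, for want of symbols and of batch labels. The groups share no clone numbers, so no pairing was fitted. Many probes are close to background: 15546 of 33012 passed the detection rule.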

Other observations

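The test in this part was chosen after the result was seen. The brighter of the identified mouse probes stood higher, relative to the rows without identifier, on the podoplanin arrays, by a size that depended on the statistic. The 75th percentile of the identified probes was 12.5% ± 1.16 of the median of those rows in the podoplanin group and 9.86% ± 0.61 in the control group (SD, n = 3 each). The ratio of the means was 1.26, with values from 11.5 to 13.8% against 9.20 to 10.4% and no overlap, and the two-sided exact permutation test gave p = 0.1, the smallest possible here. With the mean of the identified probes the ratio was 1.08, also without overlap. With their median it was 1.04 and the groups overlapped (exact permutation p = 1), with control 25 the highest array at 3.36% and the podoplanin arrays from 2.57 to 2.69%. A larger share of mouse RNA in the podoplanin pools is a candidate explanation, but the median does not bear it out. It stays open, because 3 clones against 3 cannot reach a smaller p, and because it is not known whether the rows without identifier are constant between samples.

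Among the 370 pairs with both probes detected on all 6 arrays, the differences between groups correlated at 0.296 across pairs, against 0.159 over all 750 pairs. The deviations of control 25 correlated at 0.104 in these pairs and at 0.121 over all pairs, so they did not gain with detection.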
